A study of Mus musculus with 12 samples.

How the data were processed

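RNA was measured in 12 samples of sorted mouse skin fibroblasts on Affymetrix whole-genome mouse expression arrays, 1 array per sample. Per the labels' protocols, back skin came from 7-week-old male mice with a PDGFRα-H2B-eGFP allele, in which a fluorescent histone marks nuclei of cells that express the PDGF receptor alpha, a fibroblast surface receptor. Muscle and dermal fat were scraped off, the skin lay overnight in cold trypsin, and the epidermis between the hair follicles was removed. The dermis was digested with collagenases, hyaluronidase and DNase, and fluorescent cells were collected by flow cytometry. RNA was isolated with the Qiagen RNeasy kit, amplified in 1 round with a NuGEN Pico kit and labelled with biotin. The labels gave 3 groups of 4 arrays: fibroblasts of normal wild-type skin, of inflamed skin of InvEE mice, and of papilloma-associated (tumour-associated) skin of InvEE mice. InvEE mice carry an activated form of the kinase MEK1 under the involucrin promoter, which is active in the differentiating epidermis. The labels do not say that the replicates of a group came from separate animals, so the p-values measure the spread between these samples, which may in part be technical.

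The deposited values were on a log2 scale, 1 value per probe set and array, between 2.08 and 14.96. Per the submitters' processing notes the linear-model package limma was used, with no version given. The method that turned scanned intensities into these values, their background correction and their normalization are not given in the sources used here. The medians of the normal arrays 1 to 4 were 6.63, 6.607, 6.625 and 6.633. Those of the inflamed arrays were 6.654, 6.643, 6.636 and 6.659, and those of the tumour-associated arrays 6.584, 6.543, 6.559 and 6.606. The lower quartiles of the arrays spanned 0.284 and the upper quartiles 0.276 on the log2 scale. Quantile normalization was therefore applied, by a rule that asked for it where quartiles differed by over 0.1. No pair of arrays shared more than 0.253% of identical values, and the correlation across probe sets between arrays of 1 group lay between 0.890 and 0.987, so each array was counted as its own replicate. The number of arrays limits the precision of every value.

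Of the 45101 probe sets, 64 were Affymetrix controls, 34958 were paired with exactly 1 gene symbol, 932 with several and 9211 with none in the platform annotation used here. Of those with 1 symbol, 34754 also matched a current gene entry, and no symbol needed updating. Each gene was represented by the probe set with the highest mean over the 12 arrays, which gave 18193 genes, 9012 of them with several probe sets. Of 55 called differences of named genes with other probe sets, all of these were called within 1.5 times in 18 and further apart in 14, some were called in 6 and none in 17. No dim genes were left out. No detection calls were used here. A group mean under 6.163, the limit of the lowest 40% of probe-set means, is called dim, a description added after seeing the data. Of the called differences of named genes, 27 in 23 genes had a dim group, and 2 had both groups dim. Since the background correction is not given, the sizes of these log2 differences depend on it. The lower quartiles of the normalized arrays lay between 5.301 and 5.302.

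Differences were tested with limma 3.58.1 in R 4.3.3. One linear model with 3 group means was fitted to all 12 arrays (lmFit), gene variances were moderated (eBayes), and 3 comparisons were drawn from it: inflamed against normal, tumour-associated against normal, and tumour-associated against inflamed. Tests were two-sided, and a gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over all genes). Differences are given as log2 fold changes with their standard error (SE), and group levels as mean ± standard deviation (SD) of the normalized log2 values.

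A set of 40 gene lists with 661 members, 604 of them measured, was tested with camera in limma at a preset correlation between genes of 0.01, adjusted over all lists and the 3 comparisons. Camera at an estimated correlation and the directional test of fry were run beside it. The lists held fibrillar and associated collagens, collagen and matrix cross-linking enzymes, matricellular proteins and matrix glycoproteins, basement membrane components, matrix proteases and their inhibitors, hyaluronan metabolism, myofibroblast and contractile genes, markers of the papillary dermis, of the reticular dermis and fascia and of the dermal papilla and dermal sheath, and general fibroblast identity genes. Signalling lists held the TGF-beta pathway, chemokines, cytokines and their receptors, NF-kappaB feedback and target genes, the interferon response, MHC class I and antigen processing, complement, prostaglandins, Wnt genes, BMP and hedgehog genes, and growth factors made by fibroblasts. Further lists held cell cycle, glycolysis and hypoxia, and adipogenic genes, immediate early, heat shock, ribosomal protein and oxidative phosphorylation genes, and markers of keratinocytes, macrophages, MHC class II and dendritic cells, neutrophils, T and NK cells, mast cells, endothelium, pericytes and smooth muscle, Schwann cells and melanocytes, skeletal muscle and erythrocytes. Some genes stood in several lists.

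Genes were named by a rule. For each comparison it took the 8 largest rises and the 8 largest falls among called genes whose 2 groups did not overlap, without clone names and markers of other cell types. It added up to 4 called members of each list with the smallest adjusted p, or the member with the smallest p where none was called. It always took Pdgfra, Lox and its relatives, Tgm2, Col1a1, Acta2, Fap, Il6 and Xist. Loxl2 was not analysed here. The groups, the model, the gene lists, the naming rule and the alternatives were chosen before the data were examined, except 2 alternatives and 5 gene lists that are named as added after seeing the data.

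The alternatives were the values as deposited, median centring, shifting each array by its ribosomal protein mean, leaving out dim genes (the lowest 40% of means), other ways to choose probe sets, trended and robust variance moderation, array weights, fits of only the groups compared, the replicate number as a block, at least 2-fold or an adjusted p under 0.01, an ordinary model without moderation, and each array left out in turn. Added after seeing the data were a fit without normal array 4 and tumour-associated array 4, and a fit with the mean level of the poly-A spike controls as a covariate. Those controls are bacterial transcripts that are commonly added to the sample RNA in fixed amounts before labelling; whether and how they were added is not given in the sources used here.

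The comparison of genes was tested on simulated data for the 18193 genes with 200 of them changed. Of 100 genes changed by a log2 of 1, it recovered 16 for inflamed against normal, 20 for tumour-associated against normal and 15 for tumour-associated against inflamed. Of 100 changed by a log2 of 2, it recovered 72, 81 and 84, with 1, 2 and 1 false calls, and with no gene changed it made 0 calls by limma.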

Results

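Gene expression was measured in sorted PDGFRα-positive dermal fibroblasts of mouse back skin. The series held 12 arrays: 4 of normal wild-type skin, 4 of inflamed InvEE skin and 4 of tumour-associated InvEE skin, all of 7-week-old males. The comparisons ask how the transcriptome of dermal fibroblasts differs between normal skin, skin with an inflamed epidermis, and skin around papillomas.

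The reporter gene of the sort, Pdgfra, was well expressed in all groups, with mean log2 values of 9.94 ± 0.49 (SD, n = 4) in normal, 10.62 ± 0.22 in inflamed and 10.87 ± 0.35 in tumour-associated arrays. Col1a1, the alpha 1 chain of type I collagen, was near the top of the measured range in each group, at 14.45 ± 0.08, 14.30 ± 0.19 and 14.48 ± 0.05. Xist, the transcript of the inactive X chromosome, lay between 5.07 and 6.48 over the 12 arrays. The Y-linked genes Eif2s3y and Kdm5d lay between 8.66 and 10.1 and between 7.45 and 9.71; they were named outside the rule as further checks of the stated sex.

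The poly-A spike controls separated the inflamed arrays from both other groups, and the hybridisation controls separated them from the normal arrays. The mean of the spike controls over 12 probe sets was 8.15 ± 0.34 (SD, n = 4) in inflamed, 10.49 ± 1.20 in normal and 10.98 ± 1.05 in tumour-associated arrays. Inflamed arrays differed from normal arrays by -2.34 (log2), and tumour-associated from inflamed arrays by 2.83. Each difference had an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 arrays allow, or 0.0857 after adjustment over the control measures tested. Tumour-associated and normal arrays differed by 0.49 (exact permutation p = 0.571). The hybridisation controls, over 16 probe sets, had means of 12.81 ± 0.25 in normal, 12.30 ± 0.06 in inflamed and 12.43 ± 0.18 in tumour-associated arrays. The difference between inflamed and normal arrays was -0.51, with the same exact and adjusted p as the spikes. Tumour-associated arrays differed by -0.38 from normal (exact permutation p = 0.0571, adjusted p = 0.098) and by 0.13 from inflamed arrays (exact permutation p = 0.229). No fit with these controls as a covariate was made. The difference between 3′ and 5′ probe sets of Gapdh, a measure of RNA integrity, was highest within its group in normal array 4 (2.33), inflamed array 3 (3.29) and tumour-associated array 4 (3.79). Its mean was 1.89 ± 0.30 in normal, 2.16 ± 0.77 in inflamed and 2.73 ± 0.72 in tumour-associated arrays, with a difference of 0.84 between tumour-associated and normal arrays (exact permutation p = 0.0571, adjusted p = 0.098). The same difference of actin separated tumour-associated arrays (-0.10 ± 0.27) from normal arrays (-0.45 ± 0.05), by 0.35 with the same exact and adjusted p as the spikes, and was -0.29 ± 0.12 in inflamed arrays. It was highest in tumour-associated array 4 (0.30), and in normal array 4 (-0.42) it lay inside its group.

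**Figure D1:**
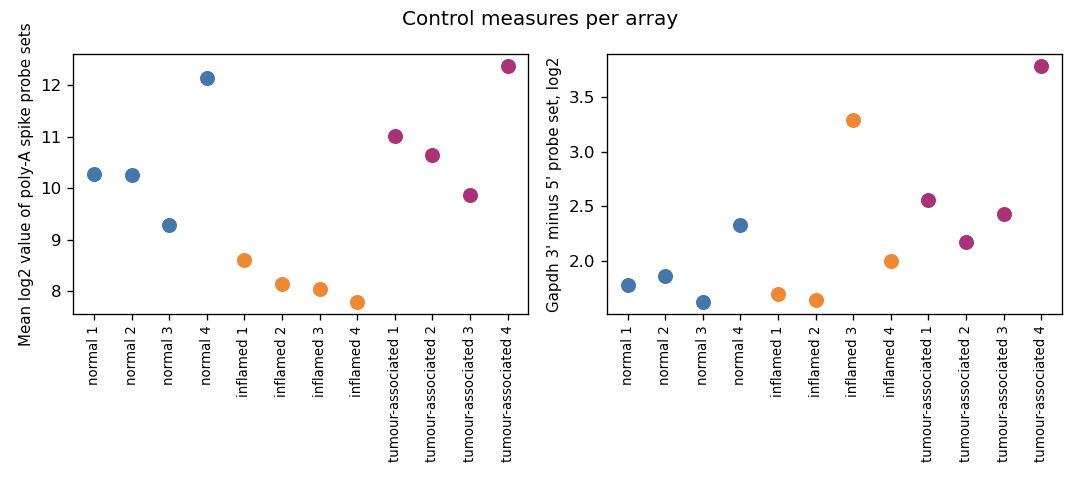
Mean log2 value of the poly-A spike controls (left) and the log2 difference between the 3′ and 5′ probe sets of Gapdh (right) for each array, 1 point per array, coloured by group (n = 4). The inflamed arrays lie between 7.79 and 8.61 for the spike controls, below all normal arrays (9.28 to 12.15) and all tumour-associated arrays (9.87 to 12.37).

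In fibroblasts of inflamed skin Tpm2, which encodes a tropomyosin of actin filaments, rose against normal skin by 2.36 ± 0.35 on the log2 scale (SE, n = 4 arrays per group; 1.74 to 2.26 on its 3 other probe sets, 1 of them called), and Tagln, the actin-binding protein transgelin, rose by 1.5 ± 0.25. Nid2, the basement membrane protein nidogen 2, rose by 2.49 ± 0.35, and the collagen chain gene Col11a1 rose by 2.71 ± 0.50. Gpha2, a glycoprotein hormone subunit, fell by 3.04 ± 0.36, from a mean log2 value of 10.50 ± 0.66 (SD) to 7.46 ± 0.31. Plin4, a lipid droplet protein, fell by 1.97 ± 0.29.

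Of 18193 genes, 97 were called in this comparison, 47 higher and 50 lower in inflamed skin, and 85 of them changed at least 2-fold. Without adjustment 2837 genes had a p under 0.05. The 2 groups did not overlap in 2779 genes, or 15.3%, where chance gives 2.86%. The median of all genes was -0.09, and of the called genes 48.5% were higher. When each array was shifted by its ribosomal protein mean, comparisons moved by -0.22 and 24.5% of the genes then called were higher. Limma called 0 genes when normal array 1, inflamed array 1 or inflamed array 2 was left out (2356, 2221 and 1961 at an unadjusted p under 0.05). It called 13 without normal array 2, 44 without inflamed array 3, 54 and 55 without tumour-associated arrays 2 and 3, and 252 without tumour-associated array 4.

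The spike controls differed between these groups too. In a fit added after seeing the data, with the spike level as a covariate, limma called 0 genes, against 2170 at an unadjusted p under 0.05. All 97 genes kept their sign there, while the median SE grew from 0.226 to 0.312 and fold changes over all genes correlated at 0.428 with those without the covariate. An ordinary linear model without moderation called 4 genes.

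Egfl6, a secreted protein with EGF repeats, rose by 2.80 ± 0.39 (SE), from 3.27 ± 0.57 (SD) to 6.07 ± 0.34. Kif26b, a kinesin family member, rose by 2.73 ± 0.40, and Tcim, a regulator of transcription and immunity, rose by 2.56 ± 0.39. Pawr, a pro-apoptotic regulator, rose by 2.93 ± 0.50 on the probe set used, while its other probe set gave 0.26 and was not called. Among the falls, Pik3r6, a regulatory subunit of phosphoinositide 3-kinase, fell by 2.85 ± 0.39, and Slc6a7, a proline transporter, fell by 2.71 ± 0.50. C1qtnf3, a secreted C1q-related protein, fell by 2.64 ± 0.40, Nat8f3 fell by 2.38 ± 0.37 and Adgrg2, an adhesion receptor, fell by 2.31 ± 0.39. Iqgap2 fell by 2.39 ± 0.42 (-1.24 without normal array 4, not called). As the probe set was chosen again in that fit, -1.24 may come from the other probe set of Iqgap2. Gng13, a G protein subunit, fell by 2.65 ± 0.44, where its other probe set gave -0.35 and was not called. The other probe sets of Tcim (1.07), Iqgap2 (-1.17), Nat8f3 (-1.71) and Adgrg2 (-1.60) were not called either. Egfl6 was dim in both groups, Tcim and Pawr in normal and Iqgap2 in inflamed arrays, so the sizes of these changes depend on how background was treated.

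Of the 14 measured myofibroblast and contractile genes, 4 rose and none fell over all genes, while 10 were higher and 1 lower when adjusted over the list alone. The list's median was 1.40 (adjusted p = 4.0e-08 by camera; adjusted p = 0.0696 at an estimated correlation). Cnn2, a calponin, rose by 1.58 ± 0.27. Acta2, smooth muscle actin, was 2.99 ± 0.54 higher on the probe set used (adjusted p = 0.0368, range over the alternatives 0.00745 to 0.946). Its other 2 probe sets gave -0.05 and 0.19, and probe sets without known cross-matching gave -0.05.

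Of 14 fibrillar and associated collagens 3 rose, also when adjusted over the list alone. They were Col11a1, Col6a3 (1.16 ± 0.17) and Col12a1 (0.99 ± 0.15, or 2.63 without normal array 4), whose 3 other probe sets gave 0.09 to 3.02, 1 of them called. The list's median was -0.04, its mean 0.39 and its test ran upward (adjusted p = 0.504 at an estimated correlation). The median turned positive without inflamed array 1 (0.08) or 2 (0.05) and lay between -0.02 and -0.01 without normal array 1, 2 or 3 or inflamed array 4. The camera call was lost without inflamed array 3 (-0.17) or tumour-associated array 4 (-0.04). Of 15 basement membrane components Nid2 rose, of 15 TGF-beta pathway genes Pmepa1, a target and feedback inhibitor of the pathway, rose by 0.87 ± 0.16 (0.61 and 0.79 on its other probe sets, not called), and of 18 glycolysis and hypoxia genes Hk2, a hexokinase, rose by 1.03 ± 0.17. Adjusted over the list alone, these lists had 1, 5 and 2 higher members, and the TGF-beta list 2 lower members. Plin4 was the 1 of 16 adipogenic genes that fell. For these 4 lists the adjusted p was 0.520, 0.374, 0.272 and 0.371 at an estimated correlation.

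Markers of the hair follicle mesenchyme leaned upward without any member past the test over all genes. Of 13 dermal papilla and dermal sheath markers, 12 had positive values and 10 were higher when adjusted over the list alone. Their median was 1.67 (adjusted p = 4.5e-10 by camera; adjusted p = 0.163 at an estimated correlation). The member with the smallest p was Sox18, a transcription factor, at 2.29 ± 0.47 (adjusted p = 0.0589). Of 15 BMP and hedgehog genes 0 passed by limma over all genes, and 6 were higher and 1 lower when adjusted over the list alone. Their median was 0.66 (adjusted p = 0.272 at an estimated correlation), and Gli1, a hedgehog target, stood at 1.81 ± 0.43 (adjusted p = 0.0922). Of 23 cell cycle genes 0 passed over all genes and 8 were higher when adjusted over the list alone, with a median of 0.51 (adjusted p = 0.0837 at an estimated correlation). Of 21 Wnt genes 0 passed and 5 were higher and 1 lower when adjusted over the list alone (adjusted p = 0.196 at an estimated correlation). With the spike level as a covariate the papilla median was 0.82 (adjusted p = 0.0479, range over the alternatives 2.2e-17 to 0.163).

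Of 22 keratinocyte markers 2 rose, Krt15, a keratin of basal and follicle cells (1.89 ± 0.27), and Perp, a desmosome protein that was dim in normal arrays (3.50 ± 0.68), and 6 were higher when adjusted over the list alone (adjusted p = 0.229 at an estimated correlation). Of 12 pericyte and smooth muscle markers, Kcnj8, a potassium channel subunit, fell by 1.86 ± 0.27 and Ndufa4l2, a mitochondrial protein, fell by 1.12 ± 0.21. Adjusted over the list alone 3 of these were higher and 3 lower (adjusted p = 0.886 at an estimated correlation). No member of the macrophage, MHC class II, neutrophil, T cell, mast cell, endothelial, Schwann cell, skeletal muscle or erythrocyte lists passed over all genes. Adjusted over the list alone, 4 of 12 MHC class II and dendritic cell markers were lower (median -0.49, adjusted p = 0.374 at an estimated correlation), and the others had 0. Mast cell markers had a median of -0.33 (adjusted p = 0.0425 by camera; adjusted p = 0.371 at an estimated correlation).

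The remaining lists also had 0 members past the limma test over all genes. Adjusted over the list alone, 6 of 19 matricellular genes were higher and 1 lower (adjusted p = 0.490 at an estimated correlation), 3 of 15 cross-linking enzymes were higher and 1 lower (0.685), and 1 of 21 matrix proteases was higher and 4 lower (0.685). Of 9 hyaluronan genes 2 were higher (0.301), of 18 growth factors 1 was higher and 1 lower (0.369), and of 18 heat shock genes 2 were higher and 1 lower (0.490). One gene each was higher among NF-kappaB, complement, papillary and reticular dermis lists. None was past that test among chemokines, cytokines, interferon, MHC class I, prostaglandin, immediate early, ribosomal protein, oxidative phosphorylation and general fibroblast genes. Camera called ribosomal protein and oxidative phosphorylation genes (medians 0.22 and 0.28, adjusted p = 0.474 and 0.504 at an estimated correlation). The spike covariate gave -0.16, not called, and -0.25, called. All 11 MHC class I and antigen processing genes had negative values (median -0.59, adjusted p = 0.374 at an estimated correlation). Signs of median, mean and test differed in 5 of the 40 lists: collagens, cross-linking enzymes (median -0.03, mean 0.14, test upward), complement (-0.19, 0.04, upward), papillary dermis (-0.02, 0.15, upward) and pericytes (-0.04, -0.11, upward). Camera called 14 lists, of which 0 held at an estimated correlation and 5 with fry.

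Several of these camera calls changed when 1 array was left out. Without normal array 4 they ended for ribosomal proteins (median 0.10), oxidative phosphorylation (0.10) and glycolysis genes (0.12). MHC class I genes lost theirs without normal array 3 (-0.47) or inflamed array 3 (-0.43). Heat shock genes lost theirs without normal array 4 (0.20), inflamed array 1 (0.38) or 2 (0.34) or tumour-associated array 4 (0.46). Mast cell markers lost theirs without normal array 3 (-0.35), inflamed array 2 (-0.31) or 4 (-0.30) or any 1 tumour-associated array (-0.33 each). Wnt genes went from 0.43 to 0.27 without normal array 4 and keratinocyte markers from 0.65 to 0.38 without inflamed array 1, both still called. Camera also called NF-kappaB (0.33) and immediate early genes (0.27) without inflamed array 3, and basement membrane (0.39), hyaluronan (0.47) and macrophage genes (-0.48) without inflamed array 1. It called matricellular genes without normal array 2 (0.21) or 3 (0.28) or inflamed array 1 (0.35) or 2 (0.46), and skeletal muscle markers without normal array 3 (-0.23) or inflamed array 2 (-0.26). None of these 11 added calls held at an estimated correlation in the same fits, where the adjusted p lay between 0.211 and 0.527.

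The genes always reported gave no further call in this comparison. Pdgfra stood at 0.68 ± 0.25 (adjusted p = 0.225) and Loxl3 at 1.00 ± 0.24 (adjusted p = 0.0973). Lox (-0.11 ± 0.27), Loxl1 (-0.28 ± 0.22), Loxl4 (-0.13 ± 0.23), Tgm2 (0.09 ± 0.51), Col1a1 (-0.15 ± 0.13), Fap (0.83 ± 1.03), Il6 (0.71 ± 0.93) and Xist (-0.51 ± 0.19) did not pass.

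In fibroblasts of tumour-associated skin Mmp13, a collagenase, rose against normal skin from a mean log2 value of 2.78 ± 0.27 (SD, n = 4) to 10.37 ± 0.70, a change of 7.59 ± 0.29 (SE). The normal level lay below the lower quartile of every array, so the size of this change depends on how background was treated. Col12a1, a fibril-associated collagen, rose by 6.02 ± 0.15 to 13.15 ± 0.12 (SD), and Tnc, the matrix glycoprotein tenascin C, rose by 6.07 ± 0.53 to 13.24 ± 0.22. Aldh3a1, an aldehyde dehydrogenase, fell by 5.61 ± 0.41, from 11.76 ± 0.29 to 6.15 ± 0.76. Bmp4, a ligand of the BMP pathway, fell by 2.96 ± 0.24, from 11.09 ± 0.49 to 8.13 ± 0.25.

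In this comparison 1756 genes were called, 883 higher and 873 lower in tumour-associated skin, and 1270 of them changed at least 2-fold. The 2 groups did not overlap in 2507 genes, or 13.8%, where chance gives 2.86%. The median of all genes was 0.04, and of the called genes 50.3% were higher. The shift by ribosomal protein genes moved comparisons by 0.43, and 85.4% of the genes then called were higher. Leaving out 1 array gave between 1256 and 1802 calls, and the fit with the spike level as a covariate gave 2050, of which 1631 were shared with the same direction. Fitting only these 8 arrays gave 1094 calls and a threshold of 0.01 gave 757.

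Prss35, a secreted serine protease relative, rose by 7.01 ± 0.59 (SE) to 11.73 ± 1.03 (SD), and Adam12, a metalloprotease, rose by 6.14 ± 0.49. Pla1a and Pla2g7, which cleave phospholipids, rose by 5.37 ± 0.37 and 5.26 ± 0.48, and Ucn2, a peptide of the corticotropin-releasing hormone family, rose by 4.92 ± 0.27. Pik3r6 fell by 4.68 ± 0.39, Prdm8, a transcriptional regulator, by 4.34 ± 0.71, and Pcolce2, an enhancer of procollagen cleavage, by 4.08 ± 0.64. Kazald1, a secreted protein, fell by 4.02 ± 0.37, Nat8f3 by 4.01 ± 0.37 and Pla2g5, a secreted phospholipase, by 3.88 ± 0.45. Slc26a7, an anion transporter, fell by 4.44 ± 0.77 (-2.71 without normal array 1, adjusted p = 0.10, range over the alternatives 0.00017 to 0.10). Without inflamed array 3 it was -2.85, its other probe set's value. Prss35, Pla1a, Pla2g7 and Ucn2 were dim in normal arrays, and Aldh3a1, Pik3r6, Slc26a7 and Pla2g5 in tumour-associated arrays, with the same limit on their sizes. Other probe sets were called too, but lay over 1.5 times apart, for Tnc (4.02), Col12a1 (3.78 to 7.58), Pik3r6 (-2.86), Slc26a7 (-2.85), Nat8f3 (-2.51), Col8a1 (6.02 and 6.85), Plat (1.63), Pmepa1 (2.82 and 4.28) and Igf1 (3.17 to 4.53).

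**Figure D2:**
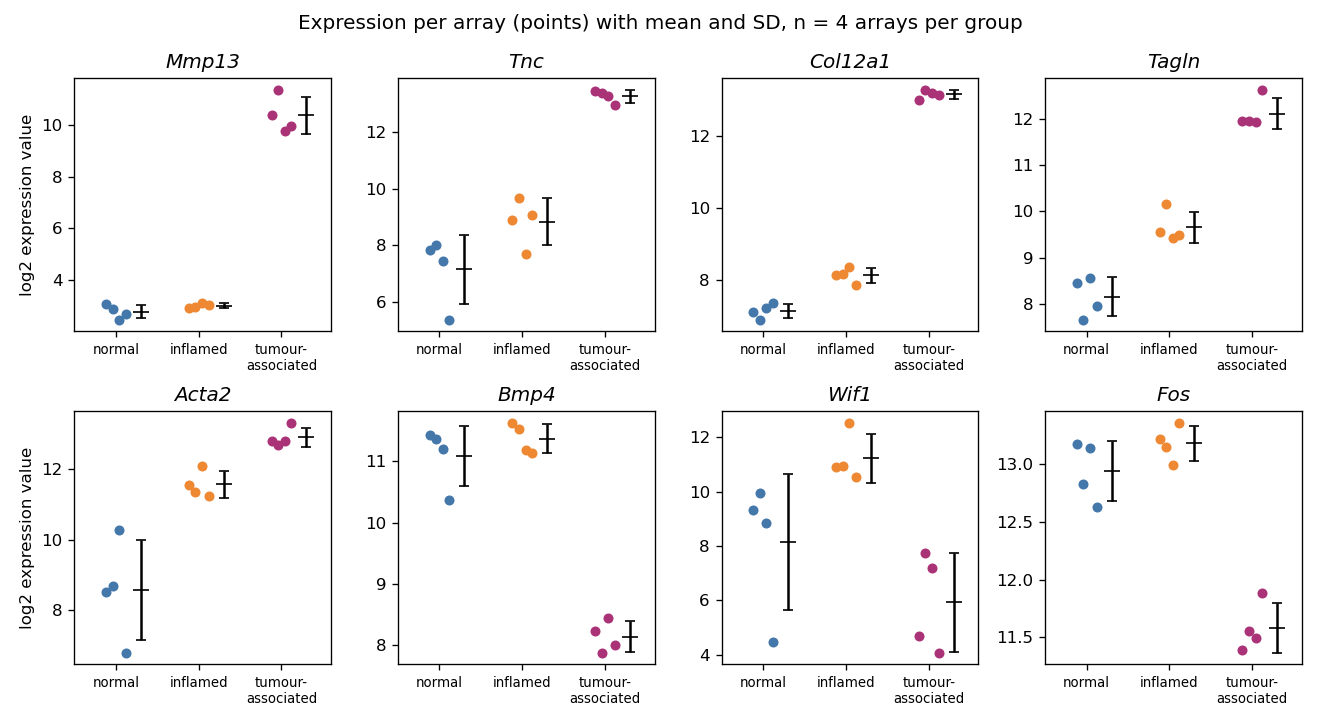
Normalized log2 values of Mmp13, Tnc, Col12a1, Tagln, Acta2, Bmp4, Wif1 and Fos in each array, by group, with the group mean and SD (n = 4) beside the points. Each panel has its own vertical range, which does not start at 0. Mmp13 lies at 2.78 ± 0.27 in normal and 10.37 ± 0.70 in tumour-associated arrays.

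Of 14 fibrillar and associated collagens, 10 rose and none fell over all genes, and 10 rose when adjusted over the list alone. Col8a1 rose by 3.13 ± 0.23 and Col6a3 by 1.91 ± 0.17, while Col1a1 stood at 0.03 ± 0.13 (adjusted p = 0.936). The list's median was 1.03 (adjusted p = 2.7e-11 by camera; adjusted p = 0.149 at an estimated correlation). Of 19 matricellular proteins and glycoproteins 9 rose and 2 fell, and 11 rose and 3 fell when adjusted over the list alone (adjusted p = 0.173 at an estimated correlation). Thbs1, thrombospondin 1, rose by 4.01 ± 0.21 and Ccn4 by 3.72 ± 0.35. Of 15 cross-linking enzymes 4 rose, or 5 adjusted over the list alone (adjusted p = 0.163 at an estimated correlation). P4ha3, a prolyl hydroxylase of collagen, rose by 4.22 ± 0.28, and Loxl3, a lysyl oxidase relative, rose by 2.76 ± 0.24. Lox (0.29 ± 0.27), Loxl1 (0.69 ± 0.22), Loxl4 (-0.29 ± 0.23) and Tgm2, a transglutaminase (-1.33 ± 0.51), did not pass.

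Of 15 basement membrane components 4 rose and 2 fell, and 6 rose and 2 fell when adjusted over the list alone (adjusted p = 0.445 at an estimated correlation). Col7a1, the anchoring fibril collagen, rose by 4.66 ± 0.25 and Nid2 by 3.94 ± 0.35. Of 21 matrix proteases and inhibitors 10 rose and none fell, and 11 rose when adjusted over the list alone, with a median of 0.45 (adjusted p = 2.3e-07 by camera; adjusted p = 0.117 at an estimated correlation). Plat, tissue plasminogen activator, rose by 2.71 ± 0.26, Adamts4, an aggrecanase, by 3.51 ± 0.42, and the inhibitor Timp1 by 3.02 ± 0.30. Of 9 hyaluronan genes 3 rose, also when adjusted over the list alone (adjusted p = 0.217 at an estimated correlation).

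Of 14 myofibroblast and contractile genes 12 rose and none fell, and 12 rose and 1 fell when adjusted over the list alone. Tagln rose by 3.96 ± 0.25, Actg2, an enteric smooth muscle actin that was dim in normal arrays, by 3.74 ± 0.31 and Palld, the actin scaffold palladin, by 3.29 ± 0.32 (0.17 to 4.02 on its 3 other probe sets, 1 not called). The list's median was 2.46 (adjusted p = 5.2e-13 by camera, and adjusted p = 0.0233 at an estimated correlation), and it was the 1 list whose call held at an estimated correlation. Acta2 rose by 4.32 ± 0.54 on the probe set used, while its other 2 probe sets gave 0.48 and 0.98 and were not called, and with probe sets without known cross-matching its value was 0.98 (adjusted p = 0.0665, range over the alternatives 4.2e-06 to 0.0665).

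Of 18 growth factors 6 rose and 1 fell, also when adjusted over the list alone (median 0.59, or 0.29 without normal array 4 and tumour-associated array 4 together; adjusted p = 0.0696 at an estimated correlation). Igf1 rose by 2.49 ± 0.17, Pdgfc by 3.74 ± 0.36 and Hgf, the hepatocyte growth factor, by 2.31 ± 0.19 on the probe set used, while its other 2 probe sets gave 0.17 and 1.51 and were not called. Of 15 BMP and hedgehog genes 2 rose and 5 fell, also when adjusted over the list alone (median -0.68, -0.44 without tumour-associated array 1 and -1.11 without those 2 arrays; adjusted p = 0.375 at an estimated correlation). Id3, a target of BMP signalling, fell by 1.14 ± 0.13, and with the shift by ribosomal protein genes its value was -0.71 (adjusted p = 0.0700, range over the alternatives 6.6e-05 to 0.0700). Of 21 Wnt genes 5 rose and 3 fell, and 6 rose and 5 fell when adjusted over the list alone (adjusted p = 0.982 at an estimated correlation). Sfrp2, a secreted Wnt modulator, rose by 4.09 ± 0.58, and Sp5, a Wnt target, fell by 1.75 ± 0.27. Of 15 TGF-beta pathway genes 3 rose and 3 fell, and 5 rose and 3 fell when adjusted over the list alone (adjusted p = 0.929 at an estimated correlation). Pmepa1 rose by 2.67 ± 0.16, and Ltbp4, a latent TGF-beta binding protein, fell by 3.00 ± 0.41.

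Of 20 interferon response genes 6 rose, and 9 rose and 1 fell when adjusted over the list alone (median 0.54; adjusted p = 0.490 at an estimated correlation). The camera call was lost without tumour-associated array 2 (0.47) or 3 (0.57), and the median was 0.85 without tumour-associated array 4. Ifit1 rose by 2.36 ± 0.28 and Oas1a by 1.55 ± 0.26, both products of the antiviral response. Of 15 NF-kappaB genes 2 rose and 2 fell, or 2 and 3 adjusted over the list alone (adjusted p = 0.929 at an estimated correlation). Ptgs2, the inducible cyclooxygenase, rose by 3.71 ± 0.57 from a dim level in normal arrays, and Icam1, an adhesion molecule, fell by 2.66 ± 0.48. Chemokines had 1 member up and 1 down of 16 (5 and 1 adjusted over the list alone, adjusted p = 0.453 at an estimated correlation), and cytokines and receptors 2 and 2 of 19 (3 and 2 adjusted over the list alone). Complement had 1 up and 1 down of 9 (1 and 2 adjusted over the list alone), and prostaglandin genes 1 and 1 of 11 (2 and 2 adjusted over the list alone). None of 11 MHC class I genes passed by either adjustment (median -0.59; adjusted p = 0.424 at an estimated correlation). Il6 stood at -0.82 ± 0.93 (adjusted p = 0.676) and Fap, a marker of activated fibroblasts, at -1.63 ± 1.03 (adjusted p = 0.40).

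Of 18 immediate early genes 8 fell and none rose, and 10 fell when adjusted over the list alone (median -0.68, adjusted p = 2.0e-07 by camera; adjusted p = 0.219 at an estimated correlation). Fos fell by 1.36 ± 0.17, Klf2 by 1.79 ± 0.18 and Klf4 by 2.82 ± 0.54. Of 14 ribosomal protein genes 1 fell, also when adjusted over the list alone (median -0.46; adjusted p = 0.490 at an estimated correlation), and the camera call was lost without tumour-associated array 4 (-0.27). Of 18 heat shock genes 2 fell and of 20 oxidative phosphorylation genes 1 rose and 1 fell, also when adjusted over the list alone. Of 23 cell cycle genes 2 rose, also when adjusted over the list alone (adjusted p = 0.374 at an estimated correlation). Hk2 rose by 1.21 ± 0.17 among 18 glycolysis genes, of which 1 more fell, and Plin4 fell by 2.47 ± 0.29 among 16 adipogenic genes, of which 1 rose and 2 fell. Adjusted over the list alone these counts were 1 and 1, and 1 and 3.

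The papillary dermis list had 2 members up and 1 down of 10, also when adjusted over the list alone, and the reticular list 2 and 1 of 10 (3 and 1 adjusted over the list alone). Cd34 fell by 2.70 ± 0.53 and Gpx3, a secreted glutathione peroxidase, rose by 1.67 ± 0.33, both in the reticular and fascia list. Of 13 dermal papilla markers 1 rose and 2 fell (2 and 4 adjusted over the list alone). Of 18 general fibroblast genes 3 rose and 2 fell over all genes, and 5 rose and 3 fell when adjusted over the list alone. Pdgfra was 0.93 ± 0.25 higher (adjusted p = 0.0349), and its other 2 probe sets, at 1.09 and 1.75, were not called. The call was lost without normal array 2 (0.93) or 4 (0.70), inflamed array 2 or 4 (0.93 each), or tumour-associated array 2 (0.96), 3 (0.80) or 4 (0.88).

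Of 22 keratinocyte markers 4 rose and none fell, and 5 rose when adjusted over the list alone (median 0.39; adjusted p = 0.504 at an estimated correlation). Krt6b, a keratin of activated epidermis, rose by 5.66 ± 0.30, from 2.69 ± 0.15 (SD), below the lower quartile of every array, to 8.35 ± 0.77, which leaves the size open. Of 12 pericyte and smooth muscle markers 1 rose and 4 fell, or 2 and 4 adjusted over the list alone (adjusted p = 0.374 at an estimated correlation). Actg2 was the member that rose, while Kcnj8 fell by 4.01 ± 0.27 and Ndufa4l2 by 3.20 ± 0.21. Csf1r, a receptor of macrophages, fell by 2.14 ± 0.45 (-1.50 and -0.48 on its other probe sets, 1 not called) and was the 1 called gene of 19 in its list. Il1r2, a decoy receptor listed with neutrophil markers, fell by 3.33 ± 0.35, and 2 others of the 10 rose. Plvap fell by 2.30 ± 0.39 among 16 endothelial markers. Of 12 MHC class II markers 1 fell (adjusted p = 0.445 at an estimated correlation), and of 13 Schwann cell and melanocyte markers 1 fell (2 adjusted over the list alone). The macrophage, neutrophil, endothelial and MHC class II counts were the same when adjusted over the list alone. None of the T cell, mast cell, skeletal muscle and erythrocyte markers passed by either adjustment. Xist stood at 0.20 ± 0.19 (adjusted p = 0.606).

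Camera called 17 lists here, of which 1 held at an estimated correlation and 11 with fry. Signs of median, mean and test differed in 7 lists. These were NF-kappaB (median 0.18, mean 0.04, test downward), complement (0.05, -0.15, downward), Wnt (-0.08, 0.14, downward), papillary dermis (-0.04, 0.19, upward), T cells (0.02, -0.03, downward), mast cells (0.05, -0.05, downward) and erythrocytes (0.12, -0.04, upward). Over the 3 comparisons camera called 47 of the 120 list tests, and the 99 other regroupings of the 12 arrays drawn gave a median of 22 and up to 41.

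With 1 array left out, further camera calls ended in this comparison. Basement membrane genes lost theirs without normal array 4 (median 0.41) or tumour-associated array 2 (0.42) or 3 (0.30), and chemokines without normal array 1 (0.80) or 4 (0.57) or tumour-associated array 2 (0.79) or 3 (0.58). Hyaluronan genes lost theirs without normal array 2 (0.27) or 4 (0.46) or tumour-associated array 2 (0.26), 3 (0.19) or 4 (0.37), and went from 0.36 to 0.21 without normal array 1. Cell cycle genes lost theirs without normal array 4 (0.39) or tumour-associated array 3 (0.30), and MHC class II markers without normal array 4 (-0.17) or tumour-associated array 2 (-0.23) or 3 (-0.20). Keratinocyte markers lost theirs without tumour-associated array 3 (0.29), and heat shock genes were called without normal array 4 (-0.19), where the adjusted p was 0.457 at an estimated correlation.

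**Figure D3:**
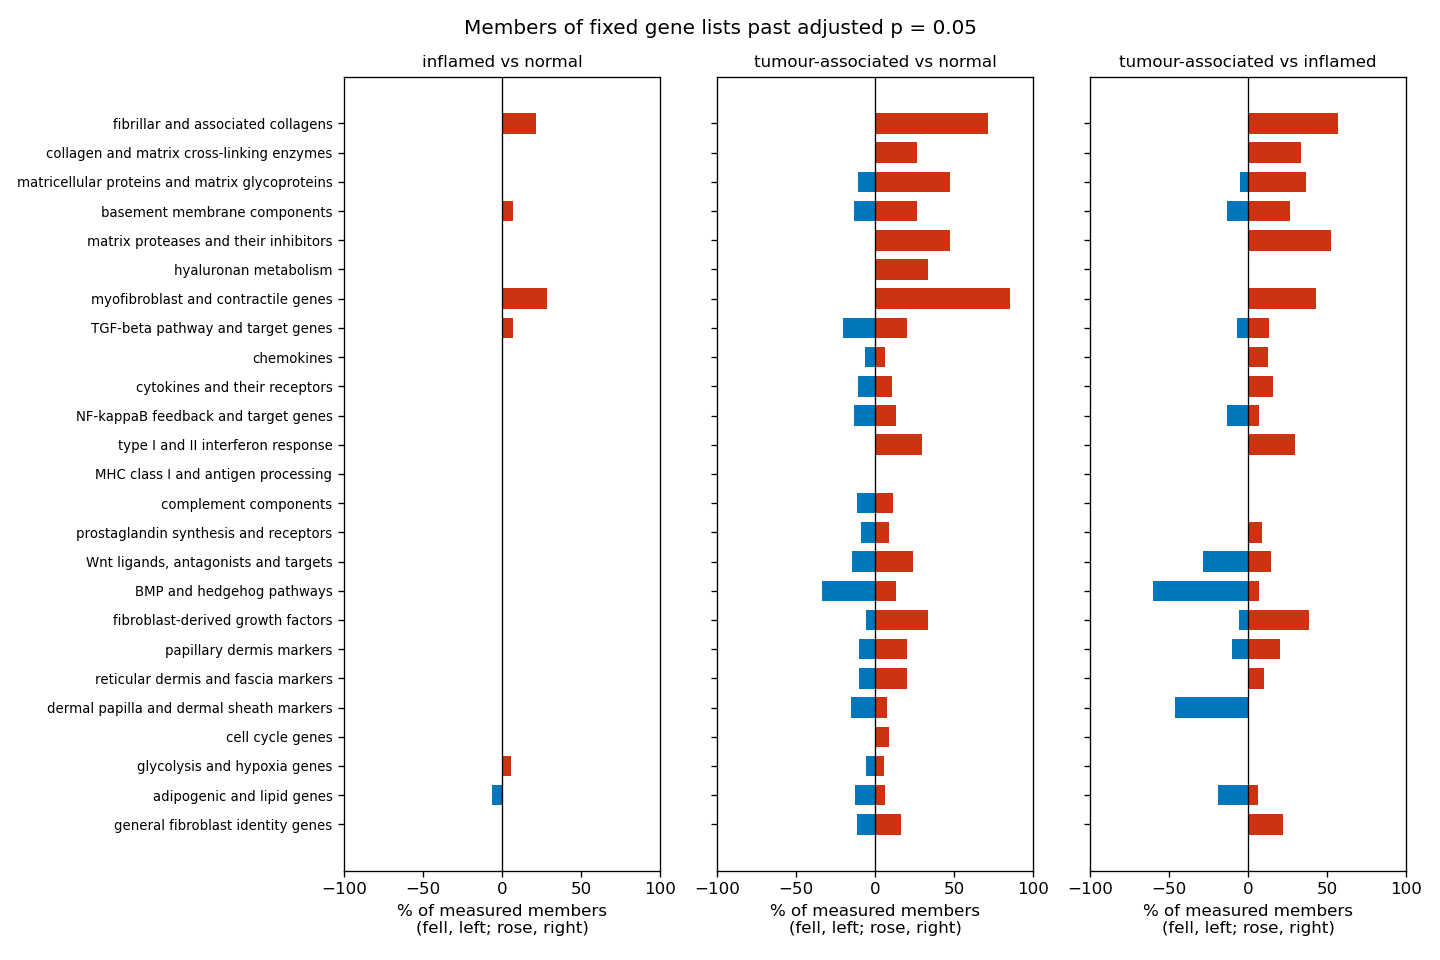
Percent of the measured members of gene lists of fibroblast and signalling genes that rose (right of 0) or fell (left of 0) at an adjusted p under 0.05 over all genes, for the 3 comparisons. In tumour-associated against normal arrays 12 of 14 contractile genes rose.

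Compared with inflamed skin, which carries the same transgene, Mmp13 rose in fibroblasts of tumour-associated skin by 7.36 ± 0.29 (SE, n = 4 arrays per group), from 3.00 ± 0.09 (SD), below the lower quartile of every array, to 10.37 ± 0.70, and Col12a1 rose by 5.02 ± 0.15, from 8.13 ± 0.21. Bmp4 fell by 3.24 ± 0.24, from 11.37 ± 0.24 to 8.13 ± 0.25. Tac1, the precursor of the neuropeptide substance P, rose by 4.46 ± 0.36 on the probe set used, from a dim level, while its other probe set gave 0.48 and was not called. Wif1, a secreted Wnt inhibitor, fell by 5.30 ± 1.14, from 11.22 ± 0.89 (SD) to 5.92 ± 1.81.

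Here 1221 genes were called, 668 higher and 553 lower in tumour-associated skin, and 809 changed at least 2-fold. The 2 groups did not overlap in 3847 genes, or 21.1%, where chance gives 2.86%. The median of all genes was 0.12 with 54.7% higher. Median centring gave 922 higher and 460 lower genes, and the shift by ribosomal protein genes, which moved comparisons by 0.65 to 97.4% higher, gave 9613 higher and 253 lower. Leaving out inflamed array 1, 2 or 4 gave 577, 621 or 718 calls. The spike controls separated these 2 groups as well, and with the spike level as a covariate, added after seeing the data, 215 genes were called (160 higher, 55 lower), 146 of them among the 1221. Of the 1221 genes 99.8% kept their sign there, and the median SE grew from 0.226 to 0.351. Of the 52 called genes named in this comparison, 32 were also called with that covariate and 20 were not.

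Prss35 rose by 6.03 ± 0.59, Tnc by 4.41 ± 0.53, Ucn2 by 4.33 ± 0.27 and Pla1a by 4.31 ± 0.37, and these calls remained with the spike covariate. Adam12 rose by 4.26 ± 0.49 (3.35 with the covariate, where it was not called). Slc15a2, a peptide transporter, fell by 4.65 ± 0.45 on the probe set used, while its other probe sets gave 0.08 to 0.24. The other large falls were not called with the covariate. They were Slc26a7 (-5.89 ± 0.77, and -4.19 with the covariate), Cd24a (-5.82 ± 1.23, -1.18), Lepr, the leptin receptor (-4.59 ± 0.61, -2.03), Tfap2a, a transcription factor (-4.34 ± 0.76, -2.29), and Wif1 (-0.93 with the covariate). Ndnf (-4.58 ± 1.00, -0.52) and Cxcr4 (-4.35 ± 0.93, -0.82) belonged to them too, and were also not called without inflamed array 1 (-4.57 and -4.25) or 2 (-4.62 and -4.21). Cd24a was not called with probe sets without known cross-matching (-4.86), and of its 2 other probe sets (-4.86 and -4.11) 1 was not called. The 3 other probe sets of Lepr gave -3.69 to -0.16, 1 of them not called. Those of Tfap2a (-3.22 and -2.48), Col8a1 (5.19 and 5.34), Pmepa1 (2.21 and 3.48), Igf1 (2.47 to 3.09) and Loxl1 (1.45) were called but lay over 1.5 times apart. Prss35 was dim in inflamed arrays, and Slc26a7, Slc15a2 and Wif1 in tumour-associated arrays.

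Of 21 matrix proteases and inhibitors 11 rose, and 15 when adjusted over the list alone (median 1.10, adjusted p = 2.8e-10 by camera; adjusted p = 0.0696 at an estimated correlation). Plat rose by 2.69 ± 0.26 (1.24 on its other probe set, not called), Timp1 by 2.50 ± 0.30 and Mmp10, stromelysin 2, by 4.20 ± 0.50 from a dim level (3.01 with the covariate, not called). Of 14 collagens 8 rose, and 10 when adjusted over the list alone (median 0.93; adjusted p = 0.163 at an estimated correlation), with Col8a1 at 3.24 ± 0.23. Of 15 cross-linking enzymes 5 rose, and 6 rose and 1 fell when adjusted over the list alone (adjusted p = 0.163 at an estimated correlation). P4ha3 rose by 4.01 ± 0.28 and Loxl3 by 1.76 ± 0.24 (1.78 with the covariate, not called). Loxl1 was 0.97 ± 0.22 higher (adjusted p = 0.0211), a call lost without inflamed array 1 (0.94) or 2 (0.95) or tumour-associated array 2 (0.87). Of 19 matricellular genes 7 rose and 1 fell, and 11 rose and 1 fell when adjusted over the list alone (adjusted p = 0.273 at an estimated correlation). Thbs1 rose by 3.31 ± 0.21, and Eln, elastin, fell by 2.09 ± 0.23, from 12.34 ± 0.20 (SD) to 10.25 ± 0.38. Of 15 basement membrane genes 4 rose and 2 fell (6 and 2 adjusted over the list alone), with Col7a1 at 4.08 ± 0.25. Of 9 hyaluronan genes 0 passed by limma over all genes, and 4 rose and 1 fell when adjusted over the list alone.

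Of 14 contractile genes 6 rose, and 9 when adjusted over the list alone (median 1.10, adjusted p = 1.2e-06 by camera; adjusted p = 0.0696 at an estimated correlation). Tagln rose by 2.46 ± 0.25 and Actg2 by 2.43 ± 0.31, while Acta2 stood at 1.33 ± 0.54 (adjusted p = 0.143). Of 18 growth factors 7 rose and 1 fell, or 7 and 2 adjusted over the list alone (adjusted p = 0.196 at an estimated correlation). Hgf rose by 2.85 ± 0.19, from 6.85 ± 0.22 (SD) to 9.70 ± 0.27, and Igf1 by 2.02 ± 0.17. The other 2 probe sets of Hgf gave 0.39 and 1.49 and were not called. Of 20 interferon genes 6 rose, and 12 when adjusted over the list alone (median 0.67, or 1.02 without tumour-associated array 4; adjusted p = 0.374 at an estimated correlation), with Ifit1 at 2.85 ± 0.28.

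Of 15 BMP and hedgehog genes 9 fell and 1 rose, and 10 fell and 2 rose when adjusted over the list alone (median -1.58, adjusted p = 7.0e-08 by camera; adjusted p = 0.161 at an estimated correlation). Bambi, a BMP and activin decoy receptor, fell by 3.07 ± 0.39 (-2.79 with the spike covariate, not called). Grem1, the secreted BMP antagonist gremlin 1, was the member that rose, by 3.56 ± 0.45. Of 13 dermal papilla and dermal sheath markers 6 fell and none rose, and 9 fell when adjusted over the list alone (median -2.07, adjusted p = 1.3e-07 by camera; adjusted p = 0.218 at an estimated correlation). Without tumour-associated array 4 that median was -1.30. The transcription factors Sox18 and Sox2 fell by 3.96 ± 0.47 and 3.00 ± 0.38, Lef1 fell by 2.91 ± 0.41 and Hey1, a Notch target, fell by 2.77 ± 0.45, with Sox2 at 3.68 in tumour-associated arrays, below the lower quartile of every array. None of these 4 calls remained with the spike covariate (-3.03, -2.41, -2.19 and -1.42), where the list's median was -0.73 (adjusted p = 0.0826, range over the alternatives 2.2e-17 to 0.218). Of 21 Wnt genes 3 rose and 6 fell, or 5 and 9 adjusted over the list alone (median -0.43, which turned to 0.22 with the ribosomal shift; adjusted p = 0.371 at an estimated correlation). That median was -0.11 without inflamed array 3 and -0.23 and -0.26 without tumour-associated arrays 1 and 4, and camera called the list only without normal array 2 or 4 (-0.43 each) or tumour-associated array 2 (-0.48), of the arrays left out (adjusted p between 0.207 and 0.388 at an estimated correlation in those fits). Dkk3 rose by 2.34 ± 0.29 (1.91 with the covariate, not called), and Notum, a Wnt-inactivating enzyme, fell by 2.01 ± 0.26.

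Of 18 immediate early genes 8 fell, and 10 when adjusted over the list alone (median -0.95, adjusted p = 8.5e-10 by camera; adjusted p = 0.163 at an estimated correlation). Fos fell by 1.60 ± 0.17, from 13.18 ± 0.15 (SD) to 11.58 ± 0.22, and Klf2 by 1.51 ± 0.18 (-1.07 with the covariate, not called). Of 14 ribosomal protein genes 2 fell, and 8 when adjusted over the list alone (median -0.67; adjusted p = 0.265 at an estimated correlation). Of 15 TGF-beta genes 2 rose and 1 fell, or 2 and 3 adjusted over the list alone, with Pmepa1 at 1.80 ± 0.16. Of 15 NF-kappaB genes 1 rose and 2 fell, or 1 and 3 adjusted over the list alone, with Icam1 at -2.91 ± 0.48 (-1.28 with the covariate, not called). Chemokines had 2 of 16 up and cytokines and receptors 3 of 19 up, which were 3, and 3 with 1 down, when adjusted over the list alone. Prostaglandin genes had 1 of 11 up by both adjustments. Adipogenic genes had 1 up and 3 down of 16, or 2 and 5 adjusted over the list alone (median -0.16, which turned to 0.01 with median centring; adjusted p = 0.219 at an estimated correlation). Papillary markers had 2 up and 1 down of 10 by both adjustments, and reticular markers 1 up of 10, or 1 up and 1 down adjusted over the list alone. General fibroblast genes had 4 of 18 up, and 6 up and 2 down when adjusted over the list alone, among them Fbln2 at 1.68 ± 0.26 (0.69 on its other probe set, not called) and Pdpn, podoplanin, at 1.09 ± 0.18.

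Of 22 keratinocyte markers 1 rose and 1 fell, or 2 and 5 adjusted over the list alone. Krt6b rose by 5.59 ± 0.30, from a level below the lower quartile of every array, and Krt15 fell by 2.16 ± 0.27. Of 12 pericyte and smooth muscle markers 2 rose and 5 fell by both adjustments (adjusted p = 0.219 at an estimated correlation), with Kcnj8 at -2.14 ± 0.27 and Ndufa4l2 at -2.08 ± 0.21. Of 10 neutrophil markers 2 rose and 1 fell, or 3 and 1 adjusted over the list alone, where Il1r2 stood at -2.25 ± 0.35 (-1.10 with the covariate, not called). Of 16 endothelial markers 1 fell by both adjustments. Over all genes 0 members passed by limma in the MHC class I, complement, cell cycle, glycolysis, heat shock, oxidative phosphorylation, macrophage, MHC class II, T cell, mast cell, Schwann cell, skeletal muscle and erythrocyte lists. Adjusted over the list alone, 1 complement, 2 mast cell and 2 erythrocyte genes were higher, and no others. Camera called cell cycle, heat shock and oxidative phosphorylation lists lower (adjusted p = 0.445, 0.374 and 0.504 at an estimated correlation). The spike covariate gave medians of 0.08, 0.06 and 0.32 (called). Pdgfra (0.25 ± 0.25), Lox (0.40 ± 0.27), Loxl4 (-0.17 ± 0.23), Tgm2 (-1.42 ± 0.51), Col1a1 (0.18 ± 0.13), Fap (-2.46 ± 1.03) and Il6 (-1.53 ± 0.93) did not pass. Xist, dim in both groups and not called on its other 2 probe sets (0.35 and 0.36), was 0.71 ± 0.19 higher (adjusted p = 0.0468, range over the alternatives 0.0067 to 0.712). The call was lost in 15 of 24 alternatives, such as without normal array 1, 2 or 3 (0.71 each), any 1 inflamed array (0.68 to 0.76) or tumour-associated array 1 (0.74).

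Camera called 16 lists in this comparison, of which 0 held at an estimated correlation and 13 with fry. Signs of median, mean and test differed in 4 lists: MHC class I (median 0.01, mean -0.08, test downward), complement (0.02, -0.18, downward), prostaglandins (0.28, -0.12, downward) and papillary dermis (-0.06, 0.03, downward).

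Some of these camera calls also changed when 1 array was left out. Growth factors, with a median of 0.20, lost theirs without normal array 4 (0.20), inflamed array 4 (0.13) or tumour-associated array 2 (0.34) or 3 (0.31). Their median was 0.34 without inflamed array 1 or 2, 0.13 without tumour-associated array 1 and 0.0052 without tumour-associated array 4. Adipogenic genes lost theirs without any 1 normal array (-0.16 each), inflamed array 3 (-0.04) or tumour-associated array 2 (-0.12) or 3 (-0.22), and had -0.33 without tumour-associated array 1. Cell cycle genes went from -0.34 to -0.11 without inflamed array 2, -0.22 without tumour-associated array 1, -0.20 without 2 and -0.24 without 4, and were not called there. They had -0.22 without inflamed array 4 and -0.215 without tumour-associated array 3. Pericyte markers, with a median of -0.18, lost their call without normal array 4 (-0.18) or tumour-associated array 2 (-0.07) or 3 (-0.15). They had -0.35 and -0.28 without inflamed arrays 1 and 2 and -0.49 without tumour-associated array 4. Oxidative phosphorylation genes went from -0.33 to -0.18, not called, without tumour-associated array 4. Camera called chemokines without tumour-associated array 4 (0.88) and keratinocyte markers without inflamed array 3 (-0.45) or tumour-associated array 3 (-0.46). It called skeletal muscle markers without normal array 3 or 4 (0.28 each), inflamed array 2 (0.30) or tumour-associated array 2 (0.29) or 3 (0.34). In those fits the adjusted p of these 3 lists lay between 0.382 and 0.608 at an estimated correlation.

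Against normal skin, 69 genes were called with the same direction in inflamed and in tumour-associated arrays, 30 higher and 39 lower in both. They included the rises of Col6a3, Col12a1, Nid2, Tagln, Pmepa1 and Hk2 and the falls of Pik3r6, Nat8f3, Plin4, Kcnj8 and Ndufa4l2. Independent lists of these sizes would share 2.28 higher and 2.40 lower genes, and 2 genes were called in opposite directions. Both comparisons use the same normal arrays. All 12 arrays were simulated 100 times as unchanged, with independent genes. In a measure added after seeing the data, the 97 and 1756 genes with the smallest p of each simulation shared 53.5 genes with the same direction on average and up to 67, against 69 observed. Lists of these sizes shared at least 69 genes in 13 of 100 regroupings of the 12 arrays, the real one included. In the simulations the mean correlation of fold changes across genes was 0.501 against 0.474 observed, and the same sign was shared by 66.7% of genes against 57.4% observed. The covariance was 0.157 against 0.044 simulated. When the normal arrays were split between the comparisons in 6 ways, between 0 and 57 genes were shared, the correlation lay between 0.17 and 0.382 and the covariance between 0.074 and 0.129. Leaving out normal array 1 or inflamed array 1 or 2 left 0 shared genes, since limma then called 0 in the inflamed comparison. Leaving out normal array 2, inflamed array 3 or tumour-associated array 2, 3 or 4 left 11, 28, 40, 38 or 153. The spike covariate also left 0, as did a threshold of 0.01, while an ordinary linear model shared 3. Of the 1756 genes called between tumour-associated and normal arrays, 709 were also called in the same direction against inflamed arrays.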

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

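The tests of RNA input, RNA integrity, array scaling, isolation stress, single inflamed arrays, keratinocyte RNA and shared genes in lists of matched size below were chosen only after the results they bear on had been seen, and so were the fits without 2 arrays and with the spike covariate; the regroupings, the test of other cell types in the 2 atypical arrays and that of the second follicle set were set before. Of 324 groups of 4 arrays tested for the named genes and 6 array measures, 20 held an array far from the other 3, where chance gives about 1 in 20 groups, or 16.2. In normal array 4, Tgm2 (7.88, others 9.996 to 10.17), Sp5 (7.39, others 8.34 to 8.47), Lepr (7.88, others 10.16 to 10.35), Ndnf (5.78, others 10.08 to 10.96), Cxcr4 (5.94, others 9.10 to 9.71), Lef1 (7.71, others 9.61 to 9.71) and Sox2 (4.16, others 5.20 to 5.38) were low. In inflamed array 3, Slc6a7 (6.89, others 9.08 to 9.35), Klf4 (11.48, others 12.30 to 12.45), Plvap (7.63, others 9.25 to 9.47) and Grem1 (7.30, others 8.88 to 8.97) were low and Fap (10.61, others 9.33 to 9.37) was high. In tumour-associated array 4, Tagln (12.63, others 11.93 to 11.96) and Igf1 (13.53, others 13.32 to 13.33) were high, and Ifit1 (9.29, others 10.21 to 10.25) and Klf4 (7.78, others 10.30 to 10.70) were low. In inflamed array 2, Timp1 was high (9.68, others 8.95 to 8.98) and Mmp10 low (5.77, others 5.99 to 6.01). Ptgs2 was low in normal array 2 (4.10, others 5.00 to 5.11), and Krt6b was high in tumour-associated array 3 (9.51, others 7.92 to 8.001). Outside the gene values, the poly-A spike mean of the inflamed arrays lay below that of the normal and tumour-associated arrays, which were 2.34 and 2.83 higher, the hybridisation control mean of the normal arrays lay 0.51 above that of the inflamed arrays, and the actin 3′ to 5′ difference of the tumour-associated arrays 0.35 above that of the normal arrays.

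Normal array 4 and tumour-associated array 4 stood apart from their groups, with array weights of 0.284 and 0.178. RNA of the same other cell type in both is argued against: over 11 marker lists, the 3 most abundant members together lay at most 0.274 above the group's other arrays in both. Neither array was tested alone, so such RNA in a single array stays open. Less RNA entering the amplification may explain the pattern, since the spike mean of both arrays lay at least 1.36 above the highest other array of its group. RNA of lower integrity may explain tumour-associated array 4, where the 3′ to 5′ differences of Gapdh and actin lay 1.23 and 0.455 above the highest other array, but stays open for normal array 4, where Gapdh lay 0.47 above it and actin -0.033 from it; whether the mice or skin samples differed was not tested. Without both arrays limma called 219, 1920 and 1754 genes in the 3 comparisons, 79, 1345 and 1097 of them called in the same direction with all arrays.

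Immediate early genes, which respond within minutes to stimuli and to cell isolation, had a median of -0.68 in tumour-associated against normal arrays, a call lost at an estimated correlation (adjusted p = 0.219, range over the alternatives 7.1e-09 to 0.219). The amount of RNA entering the amplification stays open: the median was -0.75 with the spike covariate, but the spikes hardly separate these groups, so that fit left fold changes almost as they were (correlation 0.985 over all genes), and what the actin 3′ to 5′ difference brings was not tested. Scaling stays open as part of it, since the shift by ribosomal protein genes left a median of -0.25. Milder stress during isolation may also contribute and cannot be told apart from a difference in the skin itself: the inducible heat shock genes had a median of -0.33, past the bound first set for this explanation, but Dnajb1 stood at -0.70 and Hsph1 at 0.79 and none passed the test. That members going both ways leave this open was settled only after their median had been seen, and a difference between the tissues stays open as untested.

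The median of dermal papilla and sheath markers was highest in the inflamed arrays, though no member passed limma against normal over all genes (10 of 13 adjusted over the list alone) and both list calls were lost at an estimated correlation (adjusted p = 0.163 and 0.218, ranges over the alternatives from 2.2e-17 up to these); a single inflamed array as the cause is argued against, since the median against normal was at least 1.38 with any 1 inflamed array left out. The amount of RNA entering the amplification stays open: with the spike covariate the median moved from 1.67 to 0.82 against normal while the members' median SE grew from 0.452 to 0.626, and from -2.07 (-1.30 without tumour-associated array 4) to -0.73 in tumour-associated against inflamed arrays, where the SE grew to 0.705; the hybridisation controls differed too, and what that brings was not tested. RNA of keratinocytes of the follicle also cannot be told apart, since the 5 most abundant keratinocyte markers, Krt10, Krt5, Krt14, Dsp and Trp63, had a median of -0.99 in tumour-associated against inflamed arrays with adjusted p between 0.101 and 0.971. Against it, Krt14 (-0.04) and Dsp (-0.42), unlike Krt10, Krt5 and Trp63, barely differed there and stayed 2.38 and 3.11 above normal, where the papilla median was -0.58. Sort purity was not measured. More follicle mesenchyme among the sorted inflamed cells is a hypothesis that a second set of 12 measured markers went with: its median was 1.02 against normal, at percentile 100 of 10000 random lists, and -1.16 in tumour-associated against inflamed arrays (adjusted p = 0.034 at an estimated correlation), with 3 of its genes also in the lists fixed earlier and none in the papilla list.

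The counts of called genes were highest in the real splits, the most that 35 splits can show. In inflamed against normal arrays 1 of the 35 splits of the 8 arrays, the real one, gave 97 genes, and the highest other gave 0 by limma. In tumour-associated against normal arrays these counts were 1756 and 6, and in tumour-associated against inflamed arrays 1221 and 1. For the 69 genes shared between the comparisons with normal, these tests could not decide about chance. The count of shared calls in 100 regroupings of the 12 arrays (1 as large, the highest other 0) decides nothing, since each of the 99 others called fewer than 69 genes, at most 31, in the inflamed comparison. With lists of the observed sizes, ranked by p, 13 of the 100 regroupings shared at least as many, the real one included, and the highest other 89. For the lists 1 of 100 regroupings gave 47 calls and the highest other 41, with a median of 22 over the others.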

How the results depend on the processing

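Every alternative was set before the data were examined except the fits without the 2 atypical arrays and with the spike covariate. The number of genes called between inflamed and normal arrays was 62 with the values as deposited, 57 with median centring, 228 with the mean of a gene's probe sets, 839 with array weights, 4 with an ordinary linear model and 0 by limma at an adjusted p under 0.01, where 2837 genes had an unadjusted p under 0.05. Without the 2 atypical arrays it was 219, and with the spike covariate 0 (2170 at an unadjusted p under 0.05). The genes shared with the tumour-associated comparison numbered 45 with median centring, 163 with the mean of probe sets, 402 with array weights, 3 with an ordinary model, 150 without the 2 arrays, and 0 at an adjusted p under 0.01 and with the spike covariate. Tumour-associated against normal arrays gave 1094 calls with only those groups in the fit and 757 at an adjusted p under 0.01. Tumour-associated against inflamed arrays gave 9866 with the shift by ribosomal protein genes, by construction of a shift of 0.65 for all genes, 2813 with array weights, 809 at 2-fold, 396 at an adjusted p under 0.01 and 215 with the spike covariate. With 1 array left out the counts ran from 0 to 252 for inflamed against normal, 1256 to 1802 for tumour-associated against normal, 577 to 1582 for tumour-associated against inflamed, and 0 to 153 for shared genes. Leaving out dim genes gave 97, 1735 and 1026 calls in the 3 comparisons. Apart from the ribosomal shift and the spike covariate, the cause of these moves was not tested.

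The replicate number as a block gave 57 calls between inflamed and normal arrays and 41 shared genes. Whether the numbers pair the arrays stays open. Deviations of same-numbered arrays correlated from -0.094 to 0.078, 9.5e-05 to 0.177 and -0.009 to 0.026 in the 3 comparisons. Of 8 arrays, 5, 4 and 1 correlated best with their own number.

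Some medians of lists changed sign, the cause of which was not tested except that the ribosomal shift moves all genes alike. The collagens in inflamed against normal arrays went from -0.04 to 0.0024 as deposited and 0.31 with the mean of probe sets, and ran from -0.1725 to 0.0792 with 1 array left out, positive without inflamed array 1 or 2. Adipogenic genes in tumour-associated against inflamed arrays went to 0.0116 with median centring. With the ribosomal shift, in inflamed against normal arrays prostaglandin genes went to -0.0151 and glycolysis genes to -0.0422, and in tumour-associated against normal arrays MHC class II markers went to 0.18, pericyte markers to 0.11 and Schwann cell markers to 0.22. In tumour-associated against inflamed arrays that shift gave NF-kappaB 0.47, Wnt 0.22, cell cycle 0.31, adipogenic 0.49, heat shock 0.22, oxidative phosphorylation 0.32, keratinocyte 0.32 and pericyte genes 0.47. With the spike covariate, in inflamed against normal arrays chemokines went to -0.63, glycolysis to -0.0085, heat shock to -0.062, ribosomal proteins to -0.16 and oxidative phosphorylation to -0.25, and in tumour-associated against inflamed arrays cell cycle went to 0.0821, heat shock to 0.0613 and oxidative phosphorylation to 0.32. Among called values of named genes the sign turned only for Acta2 in inflamed against normal arrays, to -0.0505 with probe sets without known cross-matching. The spike covariate ended 47 of the calls of named genes and the ordinary model 33, and camera at an estimated correlation ended 46 of the 47 list calls. Leaving out both atypical arrays ended 9 of these 47, leaving out dim genes 16, fry 18, the spike covariate 14, the ribosomal shift 7, the mean of probe sets 5, median centring and fits of only 2 groups 4 each, probe sets without known cross-matching 3, and the block and the values as deposited 1 each. Called medians moved by over 1.5 times in 7, 1, 0, 9, 32, 6, 1, 0, 4, 0 and 2 further lists in that order, and calls were added in 0, 0, 6, 9, 8, 2, 1, 1, 0, 2 and 0.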

Other observations

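The 4 gene lists in this part and the second follicle set were chosen after other genes of the same comparisons had been seen, though their own list results had not been looked at, and the 5 were tested in all 3 comparisons with adjustment over those 15 tests. Genes of the circadian clock were lower in tumour-associated than in normal arrays: 5 of 14 fell over all genes, and 10 fell and 1 rose when adjusted over the list alone (adjusted p = 0.0527 at an estimated correlation). Per1 fell by 1.72, Per2 by 1.65, Bhlhe41 by 1.40, Cry2 by 1.38 and Tef by 1.29, while Arntl, which runs opposite to the Per genes in the clock, stood at 1.36 without passing the test over all genes. Against inflamed arrays 1 clock gene fell in tumour-associated arrays (adjusted p = 0.00289; adjusted p = 0.0812 at an estimated correlation). Of 20 enzymes of xenobiotic and aldehyde metabolism 5 fell, and 7 fell and 2 rose when adjusted over the list alone (adjusted p = 0.127 at an estimated correlation). Against inflamed arrays 1 rose and 3 fell (adjusted p = 0.135 at an estimated correlation). Ephx1, an epoxide hydrolase, fell by 2.12, Aldh2 by 2.05, Gstt1 by 1.93, Cyp4b1 by 1.63 and Mgst1 by 1.51. Of 16 target genes of the actin-regulated factors SRF and MRTF, none of them in the lists fixed earlier, 10 rose, and 12 rose and 1 fell when adjusted over the list alone, with Fhl2 at 2.1, Vcl at 2.06, Cnn3 at 1.88, Srf at 1.23 and Myh9 at 1.22. Against inflamed arrays 9 rose (adjusted p = 2.29e-05; adjusted p = 0.0263 at an estimated correlation). Of 12 cell cycle arrest genes 2 fell, Gadd45g by 1.53 and Cdkn1b by 1.08. Between inflamed and normal arrays no member of these 4 lists passed by limma over all genes (adjusted p = 0.246, 0.629, 0.00118 and 0.0794 in this order; adjusted p = 0.438, 0.795, 0.0527 and 0.233 at an estimated correlation).

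Among the 10092 probe sets not assigned to exactly 1 gene, limma called 5 between inflamed and normal arrays, 300 between tumour-associated and normal arrays and 399 between tumour-associated and inflamed arrays.

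These lists tested 4 hypotheses. That clock genes differ between the groups went with the set test (adjusted p = 0.000552), a call lost at an estimated correlation, and a difference in the hour of sampling may lie behind it but was not tested, since no hour is given in the sources used here. That detoxifying enzymes fell together went with a test of adjusted p = 0.00289, lost at adjusted p = 0.127 at an estimated correlation. A shared input of SRF and MRTF to the contractile genes was in line with the third test (adjusted p = 2.35e-09, and adjusted p = 0.00961 at an estimated correlation), which measured target transcripts and not the factors' activity. Higher growth arrest genes in tumour-associated skin were not borne out (adjusted p = 0.232, median -0.17; adjusted p = 0.406 at an estimated correlation), and against inflamed arrays the same list lay lower (median -0.57, adjusted p = 0.0036; adjusted p = 0.0812 at an estimated correlation).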
